A study of Mus musculus with 4 samples.

How the data were processed

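Gene expression was measured in mouse embryonic fibroblasts, the mixed mesenchymal cells that grow out of dissociated embryos, from FAK+/+ (wild type) and FAK-/- (knockout) mice. Per the labels' protocols, cells at passage 5 were grown in medium with 10% fetal bovine serum, were starved of serum for 24 h at 50% confluence, and were then kept with or without endothelin-1 (ET-1) for 24 h. Total RNA was extracted with Trizol, and 100 ng per sample was amplified and biotin-labelled in 2 cycles, per the labels' protocols. This kind of labelling starts at the poly-A tail of a transcript and can lose signal toward the 5' end. Each of the 4 groups (wild type or knockout, untreated or ET-1-treated) was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, a design that carries several probe sets for many genes.

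The authors deposited 1 table of log2 values per probe set, summarised by RMA per the submitters' processing notes, with the version not given in the sources used here. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a probe set. The deposited values run from 5.00 to 15.24 on the log2 scale, and the array medians lie between 8.89 and 8.92. The lowest values are higher than RMA commonly gives, so an added constant or another background step cannot be excluded, and differences of dim genes would then be understated. The table holds 45101 probe sets, 64 of them Affymetrix controls, and 0 columns of other samples.

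Probe sets were named through the platform's annotation table. It paired 34958 probe sets with 1 gene and 932 with several, and 9211 were not listed. Of those paired with 1 gene, 34754 matched the RefSeq table of the GRCm38 assembly by Entrez identifier and 0 symbols needed an update. That table was used for names only, and no coordinates are given because the deposited values carry no genome build. Each gene was represented by the probe set with the highest mean over the 4 arrays among those paired with that gene alone, which gave 18194 genes. Genes whose highest value over the 4 arrays was at or below the median of all values (log2 8.90) were left out, and 12290 genes remained. A gene kept by this filter can be dim in some arrays, and a fold against such a value is uncertain. The annotation pairs no probe set with the gene that encodes FAK, so its values are not reported here and the genotype labels were not checked against them.

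The values were used as deposited. With 1 array per group there is no spread between replicates, so a difference between 2 arrays is a value with no replicate check and no test. The following were computed for each gene: the knockout minus wild-type difference in untreated and in ET-1-treated cells, the ET-1 minus untreated difference in each genotype, and the difference between both ET-1 differences. Genes at 2-fold or more were counted. Genes were counted as different after ET-1 in wild type only when the wild-type difference was 2-fold or more. That difference also had to exceed the knockout difference by 2-fold or more in the same direction. The count with genotypes exchanged was set beside this count, and it does not measure a spread between replicates.

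One test was possible. An additive model of genotype and treatment was fitted to all 4 arrays with limma 3.58.1 (lmFit, and eBayes with an intensity trend) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over 12290 genes at a threshold of 0.05. Its only residual degree of freedom is the genotype by treatment term, to which the prior adds 2.996. Its standard errors (SE) and p-values therefore compare a difference with that term and not with a spread between cultures, and the number of arrays limits the precision of every value. The fit was tested on simulated data for the genotype comparison over 12290 genes. It recovered 97% of 100 genes changed 8-fold and 1% of 100 genes changed 2-fold, and it called 4 unchanged genes. Only 200 genes were changed there and no treatment difference was set, while the fit to the data called 1677 genes for genotype. The adjusted p-value depends on the share of genes that differ, so these rates describe the simulated setting only. The remaining computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

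The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The named genes are the 15 highest and the 15 lowest in the knockout by the smaller of both genotype differences of the same sign, the 10 highest and 10 lowest after ET-1 in each genotype, and the 5 highest and 5 lowest in both. They also include the 10 highest and 10 lowest for the difference of ET-1 differences, up to 4 members with the largest differences in each list described, members singled out by a list's name, and a short set fixed by name. Predicted and clone names were passed over, and some named genes were left out of the text. Further list members are named where they differed against the direction of their list or did not pass. Of 33 lists, 1 is not reported here, and the others hold collagens, matrix glycoproteins and crosslinkers, contractile genes, TGF-beta genes, the endothelin axis, focal adhesion genes, integrins, matrix proteases, immediate early genes, cell cycle genes, p53 targets, the p53 family with the Cdkn2 locus, cytokines, interferon response, cholesterol synthesis, hypoxia and glycolysis, the unfolded protein response, oxidant defence, Hox genes, Y-linked genes, X inactivation, neighbours of the targeted locus, imprinted genes, housekeeping genes, and markers of 8 cell types. A list's median difference was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins, which describes these arrays only. A list of 14 mesothelial markers was written after the data had been seen.

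Alternatives were no level filter, a filter at the 75th percentile of all values, quantile normalisation, subtraction of each array's median, the mean of all probe sets of a gene, thresholds of 1.5-fold and 3-fold, and other eBayes settings. Some alternatives were added after the data had been seen: leaving out the ET-1-treated wild-type array, leaving out genes that differ between untreated genotypes, and requiring every bright probe set of a gene to reach the threshold. Beyond the genotype and treatment terms of the additive model no pairing was possible, because the arrays otherwise share only the replicate number 1. Control probe sets served as quality measures. These were the 3' and 5' probe sets of Gapdh and Actb, the poly-A spike-ins that are added before labelling in the standard protocol, the hybridisation spike-ins and 18S ribosomal RNA.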

Results

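Expression of 12290 genes was compared between fibroblasts with and without FAK, each untreated or after 24 h of ET-1. FAK (focal adhesion kinase) is a tyrosine kinase that acts downstream of integrins where cells attach to matrix, and ET-1 is a peptide that signals through G protein-coupled receptors. The design asks how loss of FAK alters expression, how cells of each genotype differ after ET-1, and whether the ET-1 difference depends on FAK. Each of the 4 groups was measured on 1 array, so single differences have no error estimate. Across genes, the log2 difference between arrays had an SD of 0.68 between genotypes in untreated cells and 0.86 after ET-1, against 0.39 between the wild-type arrays and 0.23 between the knockout arrays.

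The 3' and 5' ends of control transcripts set 1 array apart. The 3' probe set of Gapdh exceeded the 5' probe set by 3.79 on the log2 scale in the ET-1-treated wild-type array and by 0.85 to 0.90 in the other arrays. For Actb the gap was 1.81 there, against 0.66, 1.30 and 1.27 in the untreated wild-type, untreated knockout and ET-1-treated knockout arrays. The 4 poly-A spike-ins had gaps of 4.10 to 6.23 in that array, each 0.80 to 1.49 above the mean of the other 3 arrays. The 5' probe set of 18S ribosomal RNA read 9.29 there and 12.90 to 13.14 elsewhere. This array enters the ET-1 difference in wild type, the genotype difference after ET-1, the difference between both ET-1 differences and every limma value averaged over treatments or genotypes. The untreated genotype difference does not use it. The 9 hybridisation spike-in probe sets were compared with untreated wild type. Their median log2 difference was -0.39 (-0.57 to -0.14) in the ET-1-treated knockout, -0.16 in the untreated knockout and -0.03 in ET-1-treated wild type. The ET-1-treated knockout array enters the ET-1 difference in the knockout and the genotype difference after ET-1. It also enters the difference between both ET-1 differences and every limma value.

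**Figure D1:**
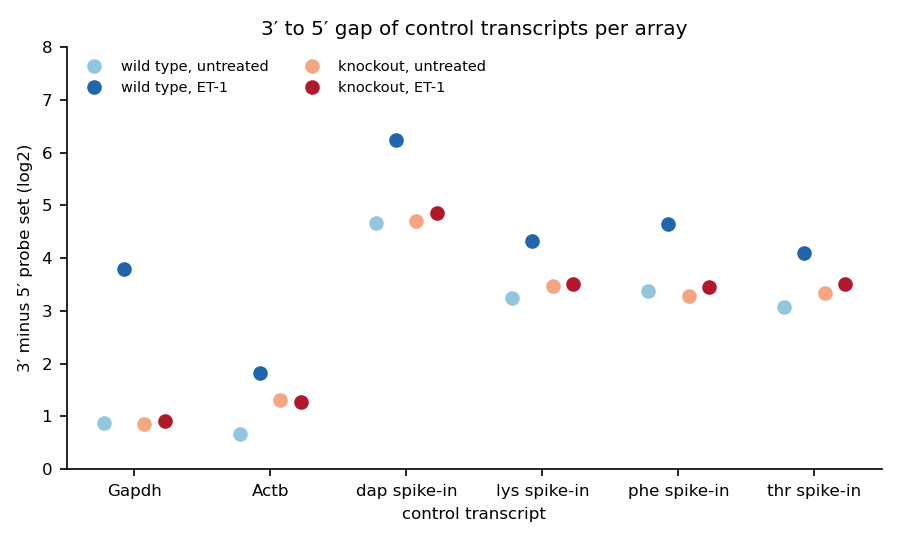
Log2 difference between the 3' and the 5' probe set of 2 endogenous transcripts and 4 poly-A spike-ins, with 1 point per array. The ET-1-treated wild-type array lies highest for all 6 transcripts, at 3.79 for Gapdh against 0.90 or less in the other arrays.

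Loss of FAK went with large differences in both treatment states. In untreated cells 587 genes were at least 2-fold higher and 564 at least 2-fold lower in the knockout than in wild type, and 427 and 492 of these differed by 2-fold or more in the same direction after ET-1. Lowest in the knockout were Zfhx4, a zinc-finger homeobox transcription factor, at 38.7-fold lower untreated and 83.7-fold lower after ET-1, and Matn2, which encodes the matrix protein matrilin-2, at 22.5-fold and 136-fold lower. By the brightest probe set the highest were Gabra4, a GABA-A receptor subunit, at 20.9-fold and 27.8-fold higher, and Nxf3, an RNA export factor, at 15.7-fold and 38.1-fold higher. The mean of all probe sets of a gene, dim ones included, put Gabra4 (2.56 and 2.68 on the log2 scale) below Nxf3 (3.97 and 5.25). The untreated and ET-1-treated knockout read 6.68 and 5.90 for Zfhx4 and 7.79 and 5.72 for Matn2, below the level filter. Wild type read 6.99 and 6.35 for Gabra4 and 7.78 and 6.78 for Nxf3, also below the filter. The folds of these genes are therefore uncertain.

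In the untreated knockout the chemokine Cxcl5 differed by -4.32 and the small proteoglycan Aspn by -4.24 on the log2 scale. The procollagen-processing enhancer Pcolce2 was 19.6-fold lower, the growth factor Fgf7 18.9-fold, the fibroblast surface protein Thy1 16.7-fold and the ligand Pdgfd 16.6-fold. Prkar2b, a regulatory subunit of protein kinase A, was 21.0-fold lower, and Sspn, a member of the dystrophin complex, 17.0-fold lower. Among the genes far above wild type, the proprotein convertase Pcsk5 was 15.5-fold higher, Lrrn4 15.1-fold, the cell adhesion protein Mpzl2 14.1-fold, the phospholipase Plce1 12.5-fold, the guidance cue Sema3d 12.4-fold, Igfbp3 11.4-fold, the endocytic receptor Lrp2 11.2-fold and the transcription factor Mycn 10.7-fold. With the mean of all probe sets, all 15 genes named as highest and all 15 named as lowest kept 2-fold in both treatment states, at smaller values for many of them. Untreated log2 values were 1.39 for Mycn (3.42 by the brightest probe set), 1.73 for Pcsk5 (3.95), 2.01 for Sema3d (3.63), 2.45 for Lrp2 (3.48), -2.13 for Pdgfd (-4.06), -2.86 for Sspn (-4.08), -2.93 for Fgf7 (-4.24) and -3.74 for Zfhx4 (-5.27), among others. For Mycn, 1 of the 2 other bright probe sets had the opposite sign.

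Averaged over treatments, 1677 of 12290 genes differed between genotypes by limma at an adjusted p under 0.05, with 811 higher and 866 lower in the knockout. Of these, 499 and 584 were also at least 2-fold higher or lower. Across genes, which are not independent replicates, the untreated and ET-1-treated genotype differences correlated with a Pearson r of 0.871. They share no array. Of the 1151 genes at 2-fold or more in untreated cells, 99.2% had the same sign after ET-1. The fit measures the difference against the genotype by treatment term, and no further line of either genotype was measured, so variation between lines was not separated from loss of FAK.

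**Figure D2:**
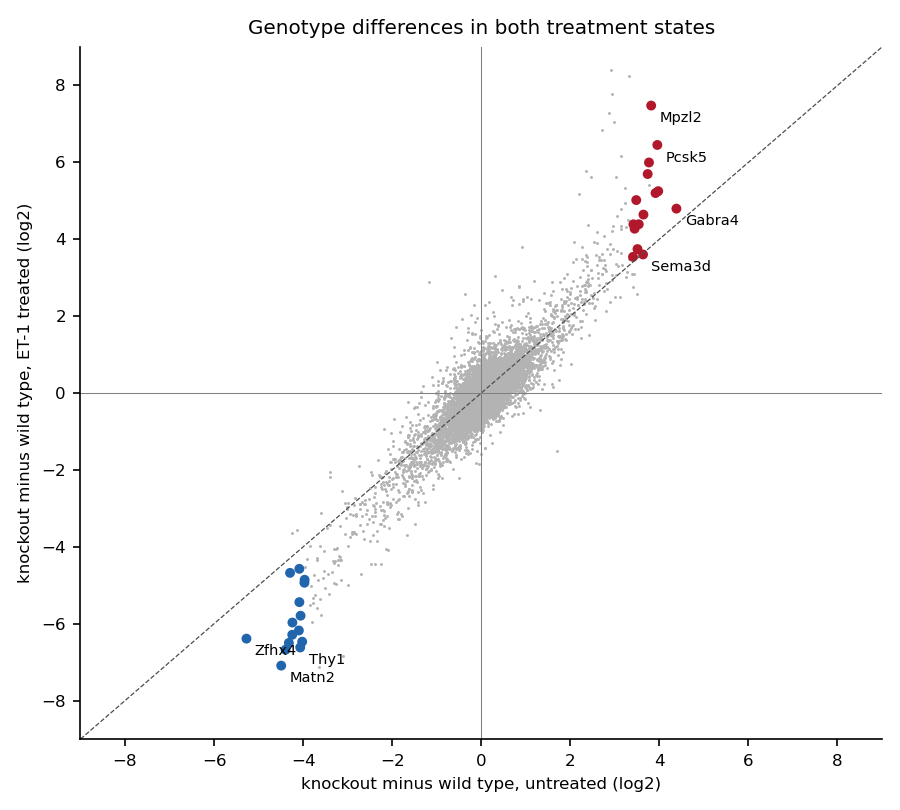
Knockout minus wild-type log2 difference of 12290 genes in untreated cells (x axis) and after ET-1 (y axis), with the 15 highest and 15 lowest named genes in red and blue and the dashed line marking equal differences. Most large differences lie beyond the dashed line, as for Mpzl2 with 3.82 untreated and 7.48 after ET-1.

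Extracellular matrix genes were lower in the knockout. The median of 19 collagen genes was -0.51 (log2) in untreated cells and -0.61 after ET-1, below all 10000 random lists in both states. By limma 9 collagens fell and 1 rose over all genes tested, and 11 and 2 did so adjusted over the list alone. Col12a1 had a difference of -3.13 ± 0.26 (SE, adjusted p = 0.00887), Col8a1 of -3.06 ± 0.36, Col6a3 of -3.04 ± 0.16 and Col1a1, a chain of the main fibrillar collagen, of -1.96 ± 0.25 (adjusted p = 0.0205). The exception was Col5a2, which rose by 2.87 ± 0.34, while Col3a1 differed by 0.02. Of 29 matrix glycoproteins and crosslinkers, 13 fell and 3 rose by limma over all genes tested (14 and 4 adjusted over the list alone), with a median of -0.32 untreated and -1.08 after ET-1. The TGF-beta-binding protein Ltbp1 fell by 4.12 ± 0.14 and periostin (Postn) fell by 4.98 ± 0.95, the thrombospondins Thbs1 (-2.79) and Thbs2 (-2.76) fell, and the small proteoglycan Dcn rose by 1.85 ± 0.12. Fibronectin (Fn1) differed by -0.01 ± 0.08 (adjusted p = 0.964) by its brightest probe set, and the mean of its probe sets gave -0.34 untreated and 0.37 after ET-1. Among 20 matrix proteases and inhibitors 5 fell and 2 rose (10 and 4 adjusted over the list alone), including Adamts5 at -2.05 and Mmp3 at -1.82.

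Contractile genes followed the same direction. The list median was -0.40 in untreated cells and -0.67 after ET-1, below all 10000 random lists, and 9 of 22 genes fell and 1 rose by limma over all genes tested (12 and 2 adjusted over the list alone). Myl9, a myosin light chain, fell by 4.88 ± 0.55, the smooth muscle actin Actg2 fell by 4.11 ± 0.45, and the calponins Cnn1 (-2.65) and Cnn2 (-2.03) also fell. Acta2, the marker actin of myofibroblasts, fell by 0.44 ± 0.07 (adjusted p = 0.033). It read 14.6 to 15.1, near the array maxima of 15.21 to 15.24, so an understated difference cannot be excluded. Of 23 TGF-beta ligands, receptors and response genes, 6 fell and 1 rose (9 and 3 adjusted over the list alone). Ccn2, a matricellular gene induced by TGF-beta, fell by 1.24 ± 0.17 (adjusted p = 0.0222), its relative Ccn3 fell by 4.68 ± 0.43 and follistatin (Fst) fell by 3.49 ± 0.27, while the receptor Tgfbr1 rose by 0.90 ± 0.15. That list's median was -0.44 untreated, below all 10000 random lists, and -0.11 after ET-1, at percentile 16.2.

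Among adhesion genes, Ptk2b, which encodes the FAK-related kinase Pyk2, rose by 2.05 ± 0.15 in the knockout (adjusted p = 0.00771), and the mean of its probe sets gave 0.96 untreated and 1.15 after ET-1. Of the 25 focal adhesion genes measured, Ptk2b was the 1 that rose, and Tgfb1i1 (Hic-5, -2.94), Tln2 (talin-2, -1.70) and Asap1 (-0.88) fell by limma over all genes tested, with 2 rising and 4 falling adjusted over the list alone. The median of that list was -0.06 in untreated cells, at percentile 8.96. Integrin genes Itgb8 (2.62) and Itgb3 (0.84) rose among 14, with 3 rising adjusted over the list alone, and the list median was -0.14, at percentile 3.88. In the endothelin list, 3 of 6 genes rose and 0 fell over all genes tested and adjusted over the list alone, and the median was 0.53 in untreated cells (percentile 99.3) and 0.37 after ET-1 (percentile 97.3). These were Edn2 (2.37 ± 0.09), Edn1, which encodes ET-1 itself (1.03 ± 0.16, adjusted p = 0.0308), and the converting enzyme Ece2 (0.90 ± 0.17). The receptor gene Ednrb differed by -0.03 ± 0.09.

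The fibroblast marker list had a median of -1.57 in untreated cells and -1.45 after ET-1, below all 10000 random lists. By limma 10 of its 14 genes fell and 0 rose (11 fell adjusted over the list alone), including Thy1 at -5.34 ± 0.65, the mesenchymal transcription factors Prrx1 at -4.29 ± 0.41 and Twist2 at -3.64 ± 0.24, and the PDGF receptor Pdgfrb at -3.99 ± 0.22. Twist1 differed by -0.04 and Cdh11 by 0.21. Of 11 epithelial markers 4 rose and 1 fell (5 and 1 adjusted over the list alone). The keratins Krt18 (4.32 ± 0.66), Krt7 (2.99 ± 0.14) and Krt8 (1.11 ± 0.17) and desmoplakin (Dsp, 2.13 ± 0.17) rose, Krt19 fell by 2.98 ± 0.23, and Epcam differed by -0.33. The epithelial list median was 0.26 untreated, at percentile 97.7.

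Positional and imprinted genes differed as well. Of 29 Hox and limb position genes, 13 fell and 1 rose by limma over all genes tested (15 and 1 adjusted over the list alone), and the median was -0.76 in untreated cells, below all 10000 random lists. Hoxd10 (-4.33 ± 0.16), Hoxa9 (-3.76 ± 0.34), Emx2 (-3.66 ± 0.22) and Hoxc8 (-3.41 ± 0.11) fell. Of 11 imprinted genes 4 fell and 1 rose (5 and 2 adjusted over the list alone). The growth inhibitor Grb10 (-4.33 ± 0.48), Meg3 (-2.83 ± 0.33), Dlk1 (-2.81 ± 0.10) and Cdkn1c (-2.60 ± 0.19) fell, and Mest rose by 2.23 ± 0.35. Peg3 was higher by 5.08 ± 1.12 but did not pass limma over all genes tested (adjusted p = 0.0648). The mean of all probe sets of Peg3 gave 1.81 untreated and 3.10 after ET-1. The imprinted list median was below all 10000 random lists in untreated cells and -0.33 after ET-1. Cytokine and chemokine genes had a median of -0.57, below all 10000 random lists, and 7 of 16 fell and 2 rose (8 and 3 adjusted over the list alone). Cxcl5 (-5.41 ± 0.55), the prostaglandin synthase Ptgs2 (-4.55 ± 0.40) and Ccl9 (-2.21 ± 0.25) fell, whereas Il33 rose by 2.82 ± 0.18. Housekeeping genes had a median of -0.01 in untreated cells and 0.01 after ET-1.

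**Figure D3:**
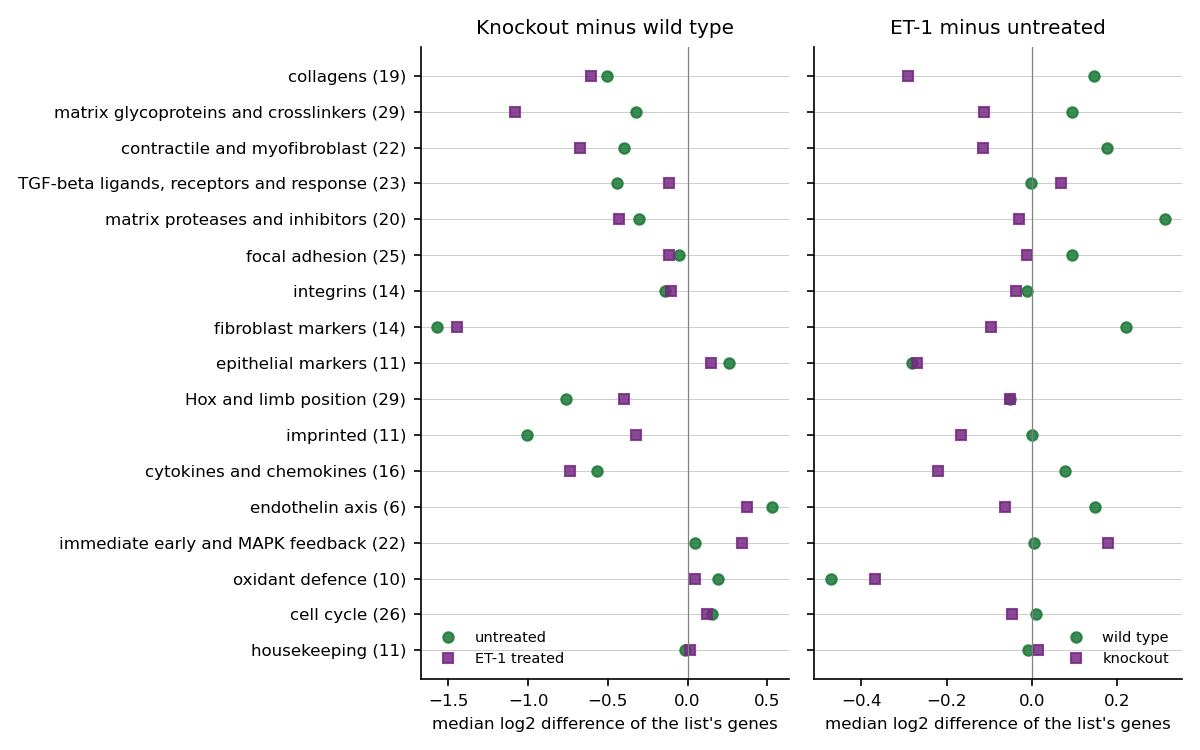
Median log2 difference of 17 of the gene lists, with the number of genes measured in parentheses, for the genotype comparison (left, circles untreated and squares ET-1-treated) and the ET-1 comparison (right, circles wild type and squares knockout). Fibroblast markers lie lowest on the left, at -1.57 and -1.45, and oxidant defence lies lowest on the right, at -0.47 and -0.37.

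The genes that differed after ET-1 in both genotypes were few. At 2-fold or more, 4 genes were higher in both and 1 was lower in both. The 4 were Rnf157, a ubiquitin ligase, at 2.46-fold higher in wild type and 2.68-fold in the knockout, the ATP-gated channel P2rx3 at 2.45-fold and 2.76-fold, the complement regulator Cd55 at 2.28-fold and 2.66-fold, and the immediate early transcription factor Egr1 at 2.07-fold and 3.05-fold. The metallothionein Mt2 was 2.24-fold lower in wild type and 4.21-fold lower in the knockout. With the mean of all probe sets, Rnf157 (0.33 and 0.42 on the log2 scale) and P2rx3 (0.49 and 0.99) were below 2-fold in both genotypes and Cd55 (0.66 and 1.24) in wild type. The insulin-like growth factor binding proteins Igfbp6 (2.79-fold and 1.83-fold) and Igfbp3 (2.19-fold and 1.86-fold) and the growth factor Fgf5 (1.89-fold and 2.38-fold) were also lower in both. The mean of all probe sets of Fgf5 gave -0.48 and -0.77 on the log2 scale.

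Averaged over genotypes, 0 of 12290 genes differed after ET-1 by limma, with a lowest adjusted p of 0.780, and 643 genes (5.23%) had an unadjusted p under 0.05. Under the other settings of filter, normalisation, probe set summary and eBayes the count was also 0, with 494 to 955 genes at an unadjusted p under 0.05. The only residual degree of freedom of the fit includes the array with the large 3' to 5' gap. Even P2rx3 (1.38 ± 0.10) and Rnf157 (1.36 ± 0.10) had an adjusted p of 0.780 by limma. The count of 0 therefore does not show an absence of ET-1 differences. Oxidant defence was the list with the most members passing when adjusted over the list alone. There 3 of 10 genes fell, against 0 over all genes tested. These were Mt2 (-1.62), Hmox1, the heme-degrading enzyme (-0.84), and Srxn1, sulfiredoxin (-0.68). The median of the list was -0.47 in wild type and -0.37 in the knockout, at percentiles 0.02 and 0. Epithelial markers were also low in both, with medians of -0.28 and -0.27 at percentiles 0.11 and 0. Ccl7 fell among the cytokines adjusted over the list alone (-0.60). The 2 ET-1 differences correlated with a Pearson r of 0.122 and a Spearman correlation of 0.189 across genes, which are not independent replicates.

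In wild type, 96 genes were at least 2-fold higher and 144 at least 2-fold lower after ET-1. The balance depended on the settings, with 800 higher and 519 lower at 1.5-fold, 122 and 132 with array medians subtracted, and 36 and 109 with the mean of all probe sets. The lowest were Gpm6a, a neuronal membrane glycoprotein (44.0-fold), Bex1 (27.9-fold), Frmd4b (27.8-fold), the imprinted transcription factor Peg3 (22.7-fold), the matrix protein Efemp1 (-4.25 on the log2 scale), the kinase Stk26 (18.8-fold), Mpzl2 (13.6-fold), uroplakin Upk3b (11.4-fold), the keratin Krt14 (9.48-fold) and prostacyclin synthase Ptgis (8.72-fold). In the ET-1-treated wild-type array all 10 read below the level filter, from 5.36 for Mpzl2 to 8.88 for Upk3b. Their folds and their order are therefore uncertain. Each of these 10 genes was 4.57-fold to 14.1-fold higher in the untreated knockout than in untreated wild type, and each differed by 1.21-fold or less after ET-1 in the knockout. Of all 144 lower genes, 37 (25.7%) were at least 2-fold higher in the untreated knockout, against 5.47% in genes matched on level. With the mean of all probe sets the 10 genes kept 2-fold, at -1.45 for Peg3 (-4.51 by the brightest probe set) and -2.31 for Frmd4b (-4.80) on the log2 scale. The highest were Hectd2 (3.80-fold), Myom2 (3.62-fold), the alanine transaminase Gpt2 (3.13-fold), the kinase Taok3 (3.10-fold), Ms4a4d (2.93-fold), Rgcc (2.93-fold) and the interferon-gamma receptor chain Ifngr2 (2.85-fold). With the mean of all probe sets, 4 of the 10 genes named as highest kept 2-fold, and the other 6, among them Hectd2 (0.61), Myom2 (0.999), Gpt2 (0.76), Taok3 (0.80) and Ifngr2 (0.79), did not. On the log2 scale Acta2 differed by 0.08, Ccn2 by 0.35, Col1a1 by 0.42, Fn1 by 0.20 and Edn1 by 0.20, and the mean of all probe sets gave -0.34 for Acta2 and -0.23 for Fn1. The brightest Acta2 probe set read near the maximum of both wild-type arrays (14.98 and 15.06), so an understated difference cannot be excluded.

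Among lists, p53 targets had a wild-type median of 0.40 after ET-1, at percentile 99.8, against a list median of 0.05 in the knockout. In wild type Trp53inp1 was at 1.33 and Gadd45a at 0.96. Matrix proteases had a median of 0.31 in wild type, also at percentile 99.8. Collagens had a median of 0.15 (percentile 77.4) and contractile genes of 0.18 (percentile 89.6). These values rest on the array with the 3' to 5' gap of 3.79 for Gapdh. Where a gene at 2-fold or more had other bright probe sets, 123 of 164 of them had the same sign, against 39 of 40 for the knockout. When all bright probe sets of a gene had to reach 2-fold, 16 genes remained in wild type and 5 in the knockout, of 106 and 23 by the brightest probe set among the same genes.

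In the knockout, 29 genes were at least 2-fold higher and 34 at least 2-fold lower after ET-1. The highest were apolipoprotein Apoe (3.25-fold), Egr1 (3.05-fold), Taf15 (2.98-fold), the MAPK feedback inhibitor Spry4 (2.76-fold), P2rx3 (2.76-fold), Rnf157 (2.68-fold), Cd55 (2.66-fold), the differentiation inhibitors Id3 (2.61-fold) and Id1 (2.54-fold), and the transcription factor Tbx20 (2.52-fold). The mean of all probe sets kept 5 of these 10 genes at 2-fold, and Spry4 (0.44), Tbx20 (0.57) and Taf15 (0.74) were among those below it. Immediate early and MAPK feedback genes had a median of 0.18, above all 10000 random lists, with 15 of 22 genes above 0. Besides Egr1 and Spry4, Fos was 1.13 higher on the log2 scale and Dusp4 0.90 higher. In wild type the same list had a median of 0.00, at percentile 19.2.

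The lowest after ET-1 in the knockout were the heat shock gene Hspa1b (10.2-fold), Postn (9.71-fold), Thy1 (4.29-fold), Mt2 (4.21-fold), Matn2 (4.20-fold), Myl9 (3.92-fold), the pentraxin Ptx3 (3.90-fold), Dpysl3 (3.74-fold), Prkar2b (3.59-fold) and Ifngr2 (3.23-fold). In the ET-1-treated knockout array all but Mt2 and Ifngr2 read below the level filter, from 5.72 for Matn2 to 8.36 for Ptx3. Their folds are therefore uncertain. Of these 10 genes, 7 kept 2-fold with the mean of all probe sets, and Ptx3 (-0.96 on the log2 scale), Dpysl3 (-0.90) and Ifngr2 (-0.84) did not. Mt2 and Ifngr2 were 1.39-fold and 3.24-fold higher in the untreated knockout than in untreated wild type, and the other 8 genes were 4.74-fold to 22.5-fold lower. Of the 34 lower genes, 27 (79.4%) were at least 2-fold lower in the untreated knockout, against 5.91% in genes matched on level. Collagens had a median of -0.29 after ET-1 in the knockout, below all 10000 random lists, and contractile genes of -0.12 (percentile 0.27), with Myl9 at -1.97 and Actg2 at -1.38. Without the genes that differed by 2-fold or more between untreated genotypes, a setting added after the data were seen, 14 genes were higher and 1 was lower.

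**Figure D4:**
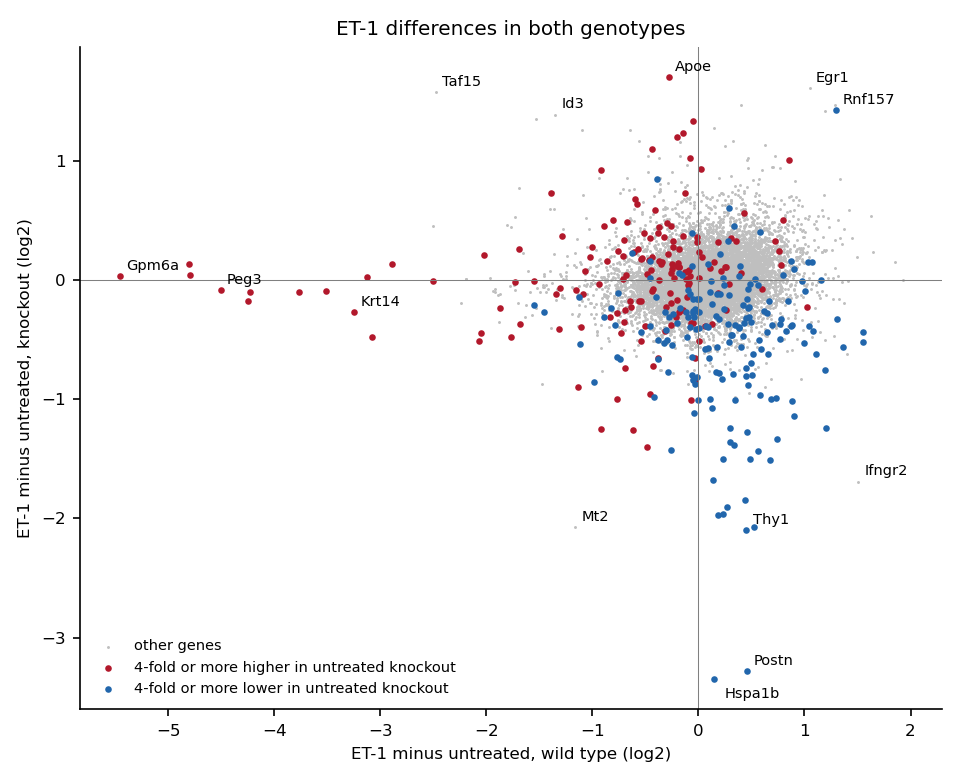
ET-1 minus untreated log2 difference of 12290 genes in wild type (x axis) and knockout (y axis), coloured by a 4-fold or larger difference between untreated genotypes. Red genes extend to the left, to -5.46 for Gpm6a, and blue genes extend downward, to -3.35 for Hspa1b.

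The difference between both ET-1 differences reached 2-fold for 356 genes, with 195 higher and 161 lower in the knockout relative to wild type. At 1.5-fold the balance was the opposite, with 623 higher and 906 lower, and with array medians subtracted it was 175 and 193. With the mean of all probe sets 213 genes reached 2-fold, 127 higher and 86 lower. Where a gene at 2-fold or more had other bright probe sets, 179 of 258 of them had the same sign, and 21.3% reached 2-fold. The SD of this value between bright probe sets of the same gene was 0.45, against 0.43 across genes. Many of the 356 genes therefore rest on 1 probe set. The highest were Gpm6a (5.49 on the log2 scale), Bex1 (4.94), Frmd4b (4.84), Peg3 (4.42) and Stk26 (4.13), with 1.30 for Peg3 and 2.55 for Frmd4b by the mean of all probe sets, and the lowest were Postn (-3.74), Hspa1b (-3.49), Ifngr2 (-3.20), Matn2 (-2.60) and Thy1 (-2.55). The highest named here read below the level filter in ET-1-treated wild type. The lowest, except Ifngr2, did so in the ET-1-treated knockout, so the sizes and order of these values are uncertain. By the stricter count, 54 genes were higher after ET-1 in wild type only and 117 were lower in wild type only, against 18 and 29 with the genotypes exchanged. The exchanged count starts from the knockout difference, which does not use the array with the large 3' to 5' gap. The knockout arrays also differed less across genes (SD of 0.23, against 0.39 for wild type). The exchanged count is therefore no measure of noise in the wild-type arrays. With the mean of all probe sets these counts were 25 and 84, against 10 and 18. Among lists, immediate early genes had a median of 0.21, at percentile 99.9, with 12 genes above and 10 below 0. Collagens had a median of -0.36, at percentile 0.14. The housekeeping list also lay high here, with a median of 0.09 at percentile 99.1, so an extreme percentile alone does not set a list apart. All 4 arrays are used up by the 4 groups, so these differences were not tested, and they include the array with the large 3' to 5' gap.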

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

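The tests of the 3' to 5' gap described here were chosen only after that gap had been seen. The Gapdh control had a 3' to 5' gap of 3.786 on the log2 scale in the ET-1-treated wild-type array, 2.91 above the mean of the other 3 arrays.

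A less complete labelling reaction of that sample is a possible explanation, in line with the spike-in test, in which 4 of 4 poly-A spike-ins had an excess gap above the largest deviation among the other arrays (0.23). Breakdown of the RNA before labelling, taken as the whole cause, was argued against by the median spike-in excess of 1.09, since in the standard protocol the spike-ins join the RNA when labelling starts. Whether some breakdown took place stayed open, because the Gapdh excess lay above all 4 spike-in excesses (0.80 to 1.49) and the Actb excess of 0.74 lay below them. The 18S ribosomal RNA was also lower in that array, by -3.85 at its 5' probe set and -1.50 at its 3' probe set.

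The other results concern 6 genes that were 2-fold or more different after ET-1 in opposite directions. The interferon-gamma receptor chain Ifngr2 went from 9.19 to 10.70 in wild type and from 10.89 to 9.19 in the knockout (log2), a difference of ET-1 differences of -3.201. That result rests on 1 probe set, since the other bright probe set had another sign in the knockout and the mean of all probe sets of Ifngr2 was 0.79 in wild type and -0.84 in the knockout. For Taf15, an RNA-binding protein, that value was 4.052, with 8.94 and 6.47 in wild type and 7.78 and 9.35 in the knockout. The mean of all probe sets of Taf15, the others being dim, gave 2.11, with -1.37 in wild type and 0.74 in the knockout, which is below 2-fold. Id1 had 2.88 and Id3 had 2.735, and both were lower after ET-1 in wild type (-1.53 and -1.35) and higher in the knockout (1.35 and 1.39). The exonuclease gene Xrn1 had 2.36, with -1.10 in wild type and 1.26 in the knockout, and the mean of its probe sets gave -0.75 and 0.69, both below 2-fold. Cth, an enzyme of cysteine synthesis, had -2.446, with 1.20 in wild type and -1.25 in the knockout. Both knockout arrays read below the level filter for Cth (7.82 untreated and 6.58 after ET-1), so its difference there is uncertain.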

How the results depend on the processing

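Leaving out the ET-1-treated wild-type array, leaving out genes that differ between untreated genotypes and requiring every bright probe set to reach 2-fold were chosen only after the results had been seen. For the values below the cause was not tested unless the construction gives it. With the mean of all probe sets of a gene, 145 genes reached 2-fold after ET-1 in wild type (240 with the brightest probe set), 40 in the knockout (63) and 213 for the difference of ET-1 differences (356), and 25 were higher in wild type only (54). Looser and stricter thresholds change such counts by construction. The balance between directions also changed after ET-1 in the knockout (29 higher and 34 lower at 2-fold, 171 and 115 at 1.5-fold) and between untreated genotypes (587 and 564, against 562 and 603 with quantile normalisation). At 1.5-fold the counts were 2453 (genotype, untreated), 3101 (genotype, ET-1), 1319 (ET-1, wild type), 286 (ET-1, knockout), 1529 (difference of ET-1 differences) and 486 (higher in wild type only), and at 3-fold they were 545, 708, 50, 13, 88 and 2. Choosing the 1083 genes that both passed limma for genotype and reached 2-fold is a subset by construction. Without the ET-1-treated wild-type array, the genotype difference averaged over treatments (1677 genes by limma) was left with the untreated difference, 1151 genes at 2-fold and no test. Without genes at 2-fold or more between untreated genotypes, 147 (ET-1, wild type), 15 (ET-1, knockout) and 187 (difference) genes remained. When 2 or more bright probe sets all had to reach 2-fold, 224 (genotype, untreated), 272 (genotype, ET-1), 16 (ET-1, wild type) and 5 (ET-1, knockout) remained. Without genes at 2-fold or more in either genotype difference, the agreement of genotype differences had a Pearson r of 0.604 (0.871 with all) and the agreement of ET-1 differences 0.281 (0.122 with all). The cell cycle list had a median of -0.0912 after ET-1 in wild type with quantile normalisation and -0.19 with the mean of all probe sets, against 0.01. Of the other list values 416 were the same, 20 stronger and 27 weaker. The named gene values were the same in 199 cases, weaker in 46 and stronger in 1.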

Other observations

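The mesothelial list and every test of an explanation in this part were chosen only after the results had been seen. Of 19 hypoxia and glycolysis genes 2 rose and 4 fell by limma over all genes tested (3 and 6 adjusted over the list alone), with the carbonic anhydrase Car9 at 2.51, the phosphofructokinase Pfkp at 2.34, adrenomedullin (Adm) at -2.13 and Slc2a1, a glucose transporter, at -1.16. The unfolded protein list had a median of 0.33 in untreated cells (percentile 99.8 on these arrays), with Sdf2l1 at 1.14 the 1 gene of 16 that rose over all genes tested (0 adjusted over the list alone). Oxidant defence genes Gsta4 (2.09), Hmox1 (1.04) and Gsta3 (1.04) rose and Srxn1 (-0.85) fell between genotypes, with the same counts adjusted over the list alone. Of 15 cholesterol synthesis genes 0 passed limma over all genes tested and 0 adjusted over the list alone, and the median was 0.15. Among 17 p53 targets Pmaip1 (2.53) and Trp53inp1 (1.64) rose and Zmat3 (-1.23) fell (3 and 1 adjusted over the list alone).

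Immediate early genes Fosl1 (-2.66) and Myc (-1.60) fell in the knockout and Klf4 (2.06) rose, with 2 of 22 rising and 3 falling over all genes tested (4 and 5 adjusted over the list alone). Ccnb2 (1.38) was the 1 of 26 cell cycle genes that rose, also adjusted over the list alone. Adipocyte markers Fabp4 (-3.46) and Pparg (-1.58) and neural markers Ncam1 (-2.22) and Map2 (-1.84) fell, with 2 and 3 of 4 genes falling adjusted over the list alone. Ifih1 (-1.55) and Cxcl10 (-0.74) fell among 9 interferon genes, over all genes and adjusted over the list alone. Csf1r (1.09) rose and Cd14 (-0.65) fell among macrophage markers, and Tnnc1 (-0.52) fell among muscle markers. Gsdmd (0.88) rose among 8 genes listed for the chromosome 15 region of the targeted locus, and B2m (-0.79) fell among housekeeping genes. Adjusted over the list alone, 2 macrophage markers, 2 muscle markers, 1 gene of the chromosome 15 list and 1 housekeeping gene passed. Bone and cartilage markers had a median of -0.05 with 0 of 6 passing in either way, and of 2 endothelial markers Kdr (-0.41) passed adjusted over the list alone. Cdkn2a read 11.26 in untreated and 8.76 in ET-1-treated wild type, the array with the large 3' to 5' gap, and was 0.45 higher after ET-1 in the knockout, and in its list of 3 genes 1 fell between genotypes adjusted over the list alone. The Y-linked genes Eif2s3y, Kdm5d and Uty were below the level filter in all 4 arrays, and Xist differed by 0.03 between untreated genotypes.

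Genes with the largest differences between genotypes were lower after ET-1 in the genotype with the lower level. Of genes at least 2-fold higher in the untreated knockout 48.9% were lower after ET-1 in wild type (43.1% of all genes), of those at least 4-fold higher 132 of 159, and of those at least 8-fold higher 92.7%. Of genes 2-, 4- and 8-fold or more lower in the untreated knockout, 62.9%, 85.8% and 92.9% were lower after ET-1 in the knockout (55.3% of all genes), so the pattern was weak at 2-fold. A small carry-over of RNA or cells between the untreated samples is a possible explanation, found from these same values. The share it would need depended on the genes chosen. Medians at 2-, 4- and 8-fold were -0.0615%, 3.59% and 4.41% of knockout in untreated wild type. Those of wild type in untreated knockout were 2.15%, 2.92% and 2.34%. At 8-fold the quartiles were 1.96% and 7.10% in wild type and 1.25% and 4.32% in the knockout. In wild type the 21 brighter of these genes had a median of 6.12% and the 20 dimmer genes 2.56%. In the knockout the 35 brighter genes had 3.46% and the 35 dimmer genes 1.56%. A carry-over would need a similar share for all genes, so whether it gives the largest drops stayed open. Neither a response to ET-1 that widens the difference between genotypes nor, for the wild-type part, the 3' bias of the ET-1-treated wild-type array was tested, and the knockout part does not use that array.

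Among genes of mesothelial cells, the lining of body cavities, Lrrn4 (4.56 ± 0.35), the transcription factor Wt1 (4.09 ± 0.45), Upk1b (3.16 ± 0.28), Bnc1 (3.09 ± 0.30) and Muc16 (2.83 ± 0.20) rose by limma, and of 14 such markers 10 rose and 1 fell over all genes tested (12 and 1 adjusted over the list alone). A mesothelial-like character of the knockout cells is a possible explanation, as the 6 markers not seen before listing had an untreated median of 1.90, at percentile 100 of random lists. A minority of mesothelial-like cells among otherwise unchanged fibroblasts was argued against, because 9 of 14 fibroblast markers were over 2-fold lower. Loss of FAK and the origin of the cells both stayed open, as no further line of either genotype was measured. After ET-1 in wild type, the 14 markers had a median of -0.79, with 14 of 14 below 0 and 6 at least 2-fold lower (-0.32 for the 6 not seen before listing, at percentile 0.44), against -0.14 in the knockout. The wild-type values rest on the array with the large 3' to 5' gap. The 14 markers also had a median of 2.52 between untreated genotypes, so the pattern of genes with large genotype differences bears on them.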
